A study of Mus musculus with 6 samples.

How the data were processed

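The series measured RNA by sequencing from the subchondral bone of the mouse mandibular condyle, the rounded end of the lower jaw that forms the temporomandibular joint. The labels give 6 libraries in 2 groups of 3, sham operation and partial discectomy, which is the removal of part of the cartilage-like disc of the joint. Groups were taken from the sample titles. The sample descriptions end in Rctrl for sham and LPD for partial discectomy, as do the table's columns of group means, and are not explained, so that whatever else these letters stand for goes with the group. The numbers before them are 1, 5 and 6 for sham and 2, 4 and 6 for partial discectomy, and the labels do not say whether the shared 6 marks the same animal. The age label reads P6w+PO2w, that is 6 weeks and then 2 weeks after the prefix PO, and does not spell out its prefixes. Surgery was on 1 side, and bone of the operated joint was taken from wild type mice, per the labels' protocols. Sequencing used a NextSeq instrument, with samples above an RNA integrity minimum, per the series' design text. That text speaks of triplicates, and the labels do not say whether the 3 libraries of a group came from separate mice. The spread between these libraries may therefore be partly technical. Which spread the p-values measure is not known, as their model is not named, and they cannot be read as the spread between mice.

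Per the submitters' processing notes, STAR 2.6.1d and the mouse build mm10 were used. The read counter, the filter on genes, the normalization and the statistical model are not given in the sources used here. What was analysed is 1 table by the authors that compares the 2 groups over 23170 genes, of which 15397 are protein-coding and 2932 are long noncoding. The second file, whose name announces filtered counts, held the positions and symbols of the same 23170 genes in the same order and no measurement, so it was not used. No values per library were analysed here, and library totals and sequencing depth are unknown. No interval or detection limit that needs a depth is given.

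In the authors' deposited table the signal columns hold a mean normalized expression value for each group, in a unit that the table does not name. The smallest group mean is exactly 1, reached by 10 genes after partial discectomy and 32 in sham, while 624 and 827 genes lie above it by at most 0.1. It was taken here as an offset of 1 added to each library's value, called the floor below, which no source used here states. The mean of both group means equalled the table's mean over 6 libraries for every gene, to within rounding. Above the floor, the values sum to 527430 for partial discectomy and 481018 for sham, a log2 ratio of 0.13. The deposited ratio is the partial discectomy mean over the sham mean, floors included, and the deposited log2 column is its logarithm. If the floor is such an offset, the ratio understates the change of genes near it. The values given with the floor subtracted rest on that reading, and most single genes are given with the floor included only. The signed fold change and its 95% limits, which were entered as a score because they take negative values, were turned here into ratios. The deposited p-value comes from a model that is not named. The deposited adjusted p equalled the Benjamini-Hochberg adjustment of those p-values over all 23170 genes. The p-values and the limits do not always fall on the same side of their thresholds, and a call here rests on the adjusted p. A gene was called changed at an adjusted p under 0.05. The table's highest value over the 6 libraries is not tied to a named library. Where it exceeded the whole sham total of a gene, it had to come from a partial discectomy library, and its share of the partial discectomy total was computed. The same was done with the groups exchanged. Genes picked in this way have a large change between the groups or 1 high library, and the highest library need not be the same from gene to gene. Among genes with a small change only those with 1 high library were picked.

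A count-based test of the 6 libraries with lists tested on values per library was planned before the data were examined. It could not be run on a table of group means, and the authors' own statistics take its place. The gene lists and the rule for named genes were fixed before the data were examined. There are 32 lists with 575 genes, of which 542 are in the table. They cover Hedgehog, Wnt, TGF-beta and BMP, and Notch signalling, bone, cartilage and joint cell types, blood cell types, muscle, fat, nerve, salivary and other epithelium, and markers of handling and RNA quality. The named genes are 20 genes chosen in advance, up to 10 genes with the largest change in each direction, and up to 4 members of each list. Some of these genes are not reported here, while the counts and tests of their lists include them. The second part needs an adjusted p under 0.05 and a mean above the floor of at least 5, and passes over unnamed gene models and immune receptor segments. Its further condition, that every library of one group lies on the same side of every library of the other, could not be checked. In that part 220 higher and 8 lower genes were eligible. A further set of gene groups, given only in the closing part, was chosen after the data were seen.

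Each list was compared with all other genes by cameraPR of limma 3.58.1 in R 4.3.3, a two-sided test on the signed normal score of the deposited p-value, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 32 lists. An estimated correlation needs values per library, so the test was repeated with preset correlations of 0.05 and 0.1. The median of each list was also placed among 10000 random lists of the same size, drawn from genes of matching mean value in 20 bins. The list test was tested on simulated scores for the 23170 genes with 200 draws. With uncorrelated genes it called 99.2% of the lists shifted by 1.5 normal units, and 3.39% of the unchanged lists had an unadjusted p under 0.05. That share rose to 12.2% when the simulated correlation was 0.05 and to 19.0% when it was 0.1. Other alternatives were a false discovery rate of 0.10, a fold change of at least 2, deposited p-values readjusted over fewer genes, limits set against another centre, and other list statistics. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

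Gene positions are those of the table, with 1 subtracted from its end column. In that form 99.1% of the 22658 symbols found in GENCODE release M21 (GRCm38, the assembly also called mm10) had the same chromosome, start, end and strand there.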

Results

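RNA from the subchondral bone of the mandibular condyle was compared between 3 libraries labelled as partial discectomy of the temporomandibular joint and 3 labelled as sham operation. Partial discectomy is used in mice to bring on joint degeneration. The series title places the comparison in the study of Hedgehog signalling in osteogenic progenitors that carry Gli1. All levels, ratios, 95% limits and p-values below are from the authors' deposited table or were computed from it, and values per library were not analysed here. A ratio is the mean after partial discectomy over the mean in sham.

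Genes of neutrophils, of the red cell lineage and of platelets were far higher after partial discectomy than in sham, and few genes were lower. At an adjusted p under 0.05 the authors' deposited table had 528 higher and 24 lower genes, so that 95.7% of the 552 calls were higher. Of the genes called higher 463 were protein-coding, and of those called lower 16. The median log2 ratio was 1.46 among the genes called higher and -1.26 among those called lower. At an unadjusted p under 0.05 the authors' deposited table had 2532 higher and 767 lower genes. The smallest adjusted p in the authors' deposited table was 0.00717. Of the 552 calls 92 were genes with a mean above the floor under 1. Readjusted over the 10286 genes with a mean above the floor of at least 5, which leaves out such genes, the deposited p-values gave 233 higher and 10 lower genes. The scale moved the balance of small differences. The deposited 95% limits lay above equal means for 2566 genes and below for 832, a share of 75.5% above. Set against the median log2 ratio of all genes, 0.08, that share was 54.9%, and set against the log2 ratio of the summed group means, 0.13, it was 40.8%. All 528 and 24 called genes kept limits on their own side of both centres.

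**Figure D1:**
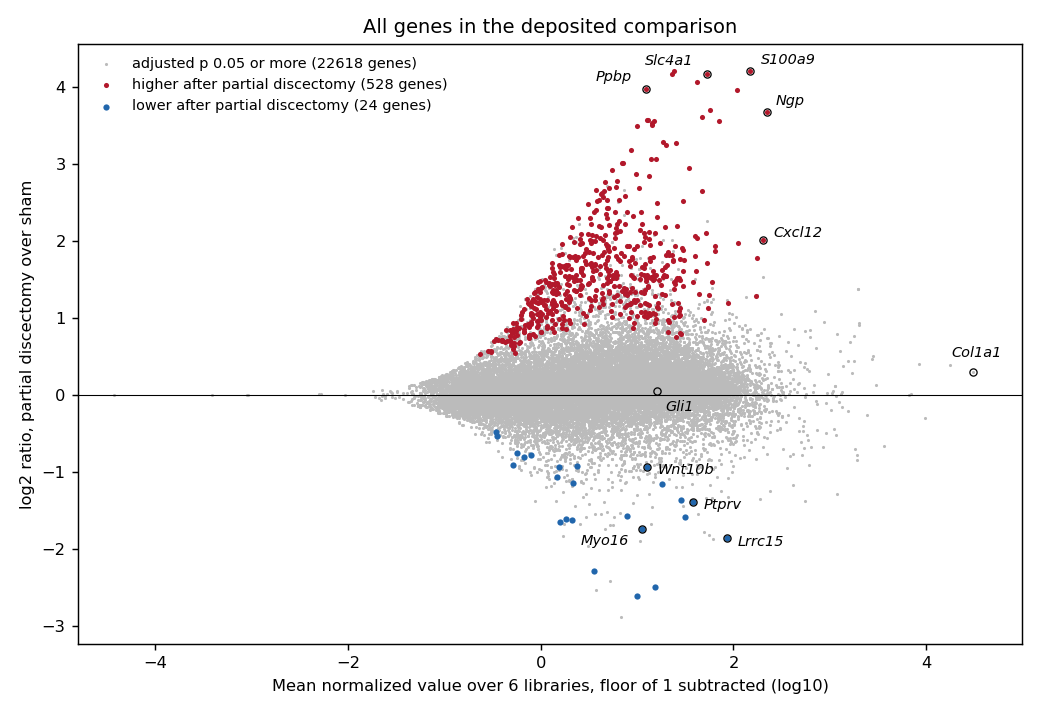
Log2 ratio of partial discectomy over sham (vertical axis) against the log10 of the mean normalized value over 6 libraries with the floor of 1 subtracted (horizontal axis), one dot per gene of the authors' deposited table. The 528 genes called higher (red) spread up to a log2 ratio of 4.20, the 24 called lower (blue) down to -2.61, and Gli1 and Col1a1 lie among the genes that were not called (grey).

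The 10 named genes with the largest rise were all genes of blood cells. The genes S100a9 and S100a8, which encode both subunits of calprotectin in neutrophils, rose 18.4-fold (95% limits 7.81 to 43.4) and 15.5-fold (6.12 to 39.3, adjusted p = 0.0125) in the authors' deposited table. The neutrophil genes Retnlg, Mmp8, Lcn2 and Ngp rose 18.4-, 16.7-, 13.0- and 12.8-fold in the authors' deposited table. Chil3, made by myeloid cells, rose 12.2-fold (5.00 to 29.6) in the authors' deposited table. Slc4a1, the anion exchanger of red cells, rose 18.0-fold (6.13 to 53.0), and the beta globin gene Hbb-bs 18.0-fold (8.95 to 36.1), per the authors' deposited table. Ppbp, which encodes a platelet chemokine, rose 15.7-fold (8.14 to 30.5) by the authors' deposited table. Sham levels were low. With the floor subtracted from the means of the authors' deposited table, Hbb-bs stood at 44.6 after partial discectomy and 1.54 in sham, a 29.0-fold difference, and Ppbp at 24.3 and 0.608. Globin genes have near-identical copies, so reads may be split between them.

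By list, 17 of 19 neutrophil genes rose, 20 of 21 erythroid genes and 9 of 12 megakaryocyte genes, and none fell. Adjusted over the list alone, the numbers in the authors' deposited table were 19, 21 and 11. The median log2 ratios were 3.51, 2.66 and 1.08, and with the floor removed 3.66, 4.02 and 2.38. Among the neutrophil genes were the granule proteins Ltf (11.7-fold, 95% limits 6.74 to 20.4; chromosome 9, 111019271 to 111042767) and Camp (11.8-fold) and the surface protein Cd177 (9.71-fold), per the authors' deposited table. Erythroid examples were Alas2, the first enzyme of red cell heme synthesis (9.52-fold, 5.69 to 15.9), Klf1, a transcription factor of the lineage (4.52-fold), and the alpha globin gene Hba-a2 (5.73-fold), all from the authors' deposited table. Tubb1 and Treml1 of the megakaryocyte list rose 2.76- and 1.91-fold in the authors' deposited table, from sham means close to the floor. The list test gave adjusted p of 8.5e-26, 4.1e-29 and 2.7e-14 for the 3 lists, and 4.3e-11, 1.0e-11 and 9.3e-08 with a preset correlation of 0.1. For the 46 called members of these lists, the highest single library held a median of 51.0% of the partial discectomy total, where an even spread gives 33.3%.

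Lymphoid genes were higher too, with fewer single genes past the threshold, and monocyte and macrophage genes were mixed. All 19 B cell genes had a ratio above 1 in the authors' deposited table, with a median log2 ratio of 1.28. Over all genes the authors' deposited table called 2 of them higher, Igll1 of precursor B cells (4.91-fold, 2.69 to 8.96) and Ighd (4.35-fold). Adjusted over the list alone there were 16. Ighm, the heavy chain of IgM, had a ratio of 2.36 (0.754 to 7.37) and the transcription factor Ebf1 one of 1.25 in the authors' deposited table. Of 18 T and NK cell genes 4 rose (16 adjusted over the list alone), with a median log2 ratio of 0.66. With the floor removed the order of both lymphoid lists turned, with medians of 1.52 for B cells and 1.89 for T and NK cells. The 4 T and NK cell genes that rose were Lck (2.74-fold), Nkg7 (3.11-fold), Ncr1 (2.29-fold) and Prf1 (1.84-fold), all with levels under 4 above the floor in the authors' deposited table. Of 19 monocyte and macrophage genes 4 rose (5 adjusted over the list alone): Ccr2 (4.98-fold), Ly6c2 (4.31-fold), Lyz2 (3.44-fold) and Itgam (3.39-fold), in the authors' deposited table. Ly6c2 has near-identical neighbours. Ccr2 and Ly6c2 mark inflammatory monocytes, and Lyz2 and Itgam are shared with neutrophils. The adjusted p of the list test was 2.0e-10 for B cells, 5.6e-11 for T and NK cells and 0.0446 for monocytes and macrophages. The monocyte and macrophage list had 13 of 19 ratios above 1 and a median log2 ratio of 0.19, at percentile 83.7 of matched random lists. Its adjusted p was 0.143 with a preset correlation of 0.05, 0.174 by rank and 0.0829 over genes with a mean above the floor of at least 1. At an unadjusted p under 0.05 the list had 7 higher and 0 lower genes. Of its macrophage members C1qa, Cd163 and Adgre1 had ratios of 0.983, 0.779 and 1.14 in the authors' deposited table. They were picked after their values were seen and do not stand for the list.

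The cell cycle list rose as a group. All 28 of its genes had a ratio above 1 in the authors' deposited table, with a median log2 ratio of 1.01 and an adjusted p of 6.6e-13 in the list test. Over all genes only the mitotic kinase Aurka was called (2.36-fold, 1.61 to 3.46, adjusted p = 0.0361), and 22 genes were called when adjusted over the list alone. Mki67, a marker of cycling cells, had a ratio of 2.89 (1.48 to 5.64) with an adjusted p of 0.106, Top2a one of 2.37 and Cenpf one of 2.01 in the authors' deposited table. The neutrophil, erythroid and megakaryocyte lists rose in the same comparison.

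No Hedgehog gene passed the threshold after partial discectomy, and the Hedgehog list as a group lay below other genes. Of 20 Hedgehog genes in the authors' deposited table none was called in either direction. At an unadjusted p under 0.05 none was higher and 5 were lower, and adjusted over the list alone there was no call. Gli1, a transcription factor and standard readout of the pathway (chromosome 10, 127329882 to 127341974), stood at 17.3 after partial discectomy and 16.7 in sham, a ratio of 1.03 (95% limits 0.688 to 1.56, adjusted p = 0.949) in the authors' deposited table. The receptor and target Ptch1 had a ratio of 0.845 (0.511 to 1.40), the ligand Ihh 1.12 (0.529 to 2.35) and the signal transducer Smo 0.823 (0.600 to 1.13) in the authors' deposited table. The inhibitor and target Hhip had a ratio of 0.614 (0.413 to 0.915, adjusted p = 0.265), and Gli3, which acts mostly as a repressor, 0.661 (0.461 to 0.947, adjusted p = 0.275), per the authors' deposited table. Gli2 was at 0.800 and Gas1, a co-receptor, at 0.742 in the authors' deposited table. The list had a median log2 ratio of -0.27 and 5 of 20 ratios above 1. The list test gave an adjusted p of 0.000136, and 0.0296 with a preset correlation of 0.1. The skeletal muscle and the fibrous and tendon lists were lower in the same comparison, with median log2 ratios of -0.43 (adjusted p = 0.0177) and -0.15 (adjusted p = 0.00673), and 0.107 and 0.0531 as adjusted p with a preset correlation of 0.05. The Hedgehog list holds activators, inhibitors and targets together, and a lower median does not give the state of the pathway.

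Bone-forming and cartilage genes showed no call. Across the osteoblast, osteocyte, chondrocyte and hypertrophic chondrocyte lists, which hold 61 different genes, the authors' deposited table had 0 calls over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there was 1, lower, in the chondrocyte list. In the authors' deposited table Runx2 and Sp7, the transcription factors that set the osteoblast lineage, had ratios of 0.877 (0.629 to 1.22) and 1.07 (0.687 to 1.67). The osteoblast products Alpl, Bglap and Col1a1 had ratios of 1.23 (0.600 to 2.50), 1.69 (0.394 to 7.27) and 1.23 (0.134 to 11.3) in the authors' deposited table. For Bglap and Col1a1 these limits leave a several-fold rise open. Bglap has near-identical neighbours, so its reads may be split. By the group means of the authors' deposited table, Col1a1 and Col1a2 made up 10.3% of the summed signal after partial discectomy and 8.97% in sham. The authors' deposited table gave a ratio of 1.81 for Dmp1 of osteocytes (0.768 to 4.28), 1.22 for Tnc, 1.61 for Ibsp and 1.74 for Mmp13 (0.912 to 3.31). Cartilage genes Col2a1, Acan, Sox9 and Col11a1 had ratios of 1.38 (0.437 to 4.36), 0.931 (0.404 to 2.15), 0.865 (0.489 to 1.53) and 1.20 in the authors' deposited table. Median log2 ratios were 0.35 for osteoblasts, 0.36 for osteocytes, 0.14 for chondrocytes and 0.19 for hypertrophic chondrocytes, with adjusted p of 0.718, 0.326, 0.795 and 0.961. Among random lists matched on mean value these medians lay at percentiles 99.98, 99.16, 78.35 and 87.06, with 18 of 22 osteoblast and 10 of 11 osteocyte ratios above 1. With the log2 ratio as the statistic the osteocyte list had an adjusted p of 0.0153, against 0.168 to 0.541 in its other alternatives. For chondrocytes the list test pointed lower while the median and mean were above 0.

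Osteoclast genes were higher as a group. All 19 had a ratio above 1, with a median log2 ratio of 0.75 and an adjusted p of 2.7e-06 in the list test, or 0.00538 with a preset correlation of 0.1. The authors' deposited table called 1 of them over all genes, Car2 (7.69-fold, 4.18 to 14.1), which is also an erythroid gene, and 2 were called adjusted over the list alone. Without the genes shared with other lists, Car2 and Mmp9, the adjusted p was 4.5e-05. That step keeps any blood cell gene that no other list holds, so it does not separate osteoclasts from blood cells. The neutrophil list rose in the same comparison. Acp5, tartrate-resistant acid phosphatase, had a ratio of 2.13 (0.974 to 4.66, adjusted p = 0.370), Ctsk, the protease that cuts bone collagen, 1.68 (0.974 to 2.91) and Mmp9 1.92 (0.898 to 4.11) in the authors' deposited table. A single library held 54.2% of the partial discectomy total of Acp5, and without it the log2 ratio with the floor removed went from 1.09 to 0.55 by the authors' deposited table. For the 5 of 19 osteoclast genes whose highest library was certain to be in that group, the median went from 1.11 to 0.78. Of 9 regulators of osteoclasts 1 rose, Il1b (2.25-fold, from 0.106 to 1.49 above the floor in the authors' deposited table), and 2 adjusted over the list alone. Tnfsf11, which encodes RANKL, had a ratio of 0.681 (0.423 to 1.10) and its decoy receptor Tnfrsf11b 0.984 (0.514 to 1.88), and Csf1 and Sema3a had 1.21 and 0.670 in the authors' deposited table. The adjusted p of that list was 0.290, and 0.0147 towards lower over genes with a mean above the floor of at least 1.

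**Figure D2:**
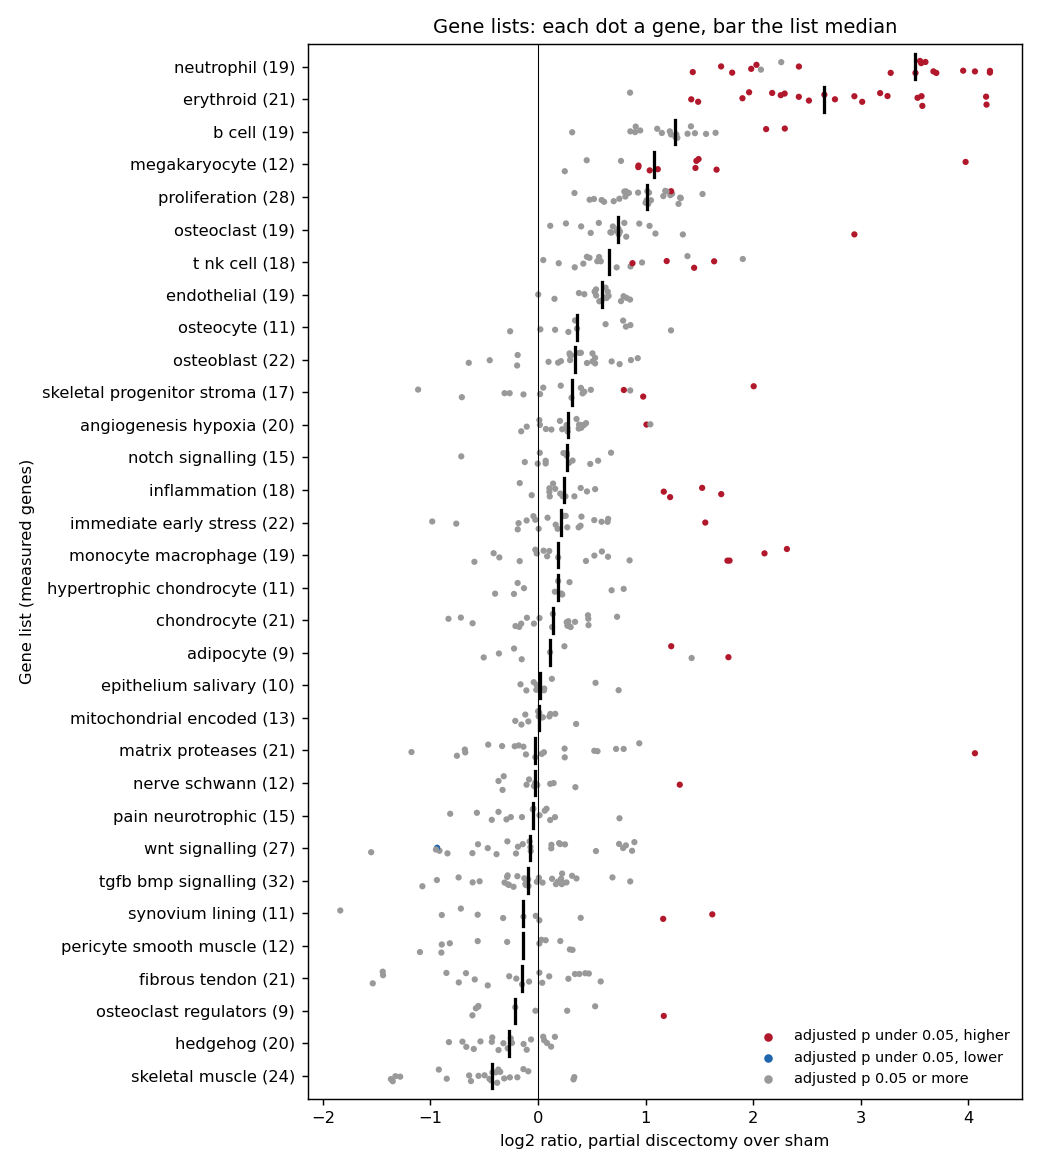
Log2 ratio of partial discectomy over sham (horizontal axis) for each measured gene of the 32 lists (vertical axis, number of measured genes in parentheses), sorted by list median (black bar), with red and blue dots for genes called higher and lower. The neutrophil, erythroid, B cell and megakaryocyte lists have medians of 3.51, 2.66, 1.28 and 1.08, while the Hedgehog list has a median of -0.27 and no called gene.

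Of 17 genes of skeletal progenitors and marrow stroma 3 rose, over all genes and adjusted over the list alone. In the authors' deposited table these were Cxcl12 (4.02-fold, 1.87 to 8.62, adjusted p = 0.0473), Ebf3 (1.97-fold) and Kitl (1.74-fold, 1.35 to 2.24). Cxcl12 encodes the chemokine that holds blood stem cells in the marrow, and Kitl the ligand of the Kit receptor. The highest library held 34.4% of the partial discectomy total of Cxcl12 in the authors' deposited table. Readjusted without the 6 blood cell lists, Cxcl12 had an adjusted p of 0.0525 and the fat cell gene Pparg one of 0.0507. Prrx1, a mesenchymal transcription factor, had a ratio of 0.612 (0.379 to 0.989) with an adjusted p of 0.372 in the authors' deposited table. The list as a whole had an adjusted p of 0.290. Of 19 endothelial genes none was called by the deposited adjusted p or adjusted over the list alone, at an unadjusted p under 0.05 there were 7 higher and 0 lower, and every ratio was above 1 (median log2 ratio 0.59, adjusted p = 3.4e-05). The authors' deposited table gave 1.49 for Cdh5 and 1.11 for Flt1. Leaving out genes shared with other lists keeps any blood cell gene that no other list holds. With that step the adjusted p of the endothelial list was 8.5e-05 in the list test. Its rise came beside those of the neutrophil, erythroid and megakaryocyte lists in the same comparison. Of 9 fat cell genes 2 rose (3 adjusted over the list alone), Fabp4 (3.41-fold, 2.44 to 4.78) and Pparg (2.36-fold), while Plin4 and Lipe had ratios of 0.705 and 1.19 in the authors' deposited table. The fat cell list had an adjusted p of 0.346, and 0.00889 towards higher over genes with a mean above the floor of at least 1. Pericyte and smooth muscle genes had no call among 12 (1 lower at an unadjusted p under 0.05, adjusted p = 0.0730). With the log2 ratio as the statistic the adjusted p of that list was 0.00254 towards lower, and 0.0289 with the floor removed. Cspg4 and Rgs5 of that list had ratios of 0.678 and 1.02 in the authors' deposited table.

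The genes called lower were few and shared no fixed list, except for Wnt10b. Wnt10b, a ligand that favours bone formation (chromosome 15, 98770712 to 98778150), had a ratio of 0.522 (95% limits 0.385 to 0.708, adjusted p = 0.0436) in the authors' deposited table. Lrrc15, a membrane protein of activated fibroblasts, fell to 0.274 of the sham mean (0.156 to 0.482), from 136 to 37.3 in the authors' deposited table. Ptprv, a receptor phosphatase made by osteoblasts, fell to 0.381 (0.256 to 0.565), and the growth factor Igf2 to 0.388 (0.265 to 0.568) in the authors' deposited table. The unconventional myosin Myo16 fell to 0.300 (0.215 to 0.418), the transcription factor Hlf to 0.334 (0.199 to 0.558), Plekha6 to 0.335 and Tppp3 to 0.448, by the authors' deposited table. Tppp3 had an adjusted p of 0.0503 when readjusted without the 6 blood cell lists. Apart from Wnt10b the Wnt list of 27 genes had no call, and Wnt10b was also the 1 lower gene adjusted over the list alone. Its members Ctnnb1, Wif1 and Lrp6 had ratios of 1.09, 1.86 and 0.868 in the authors' deposited table. The list test gave an adjusted p of 0.0329 towards lower, or 0.143 with a preset correlation of 0.05.

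**Figure D3:**
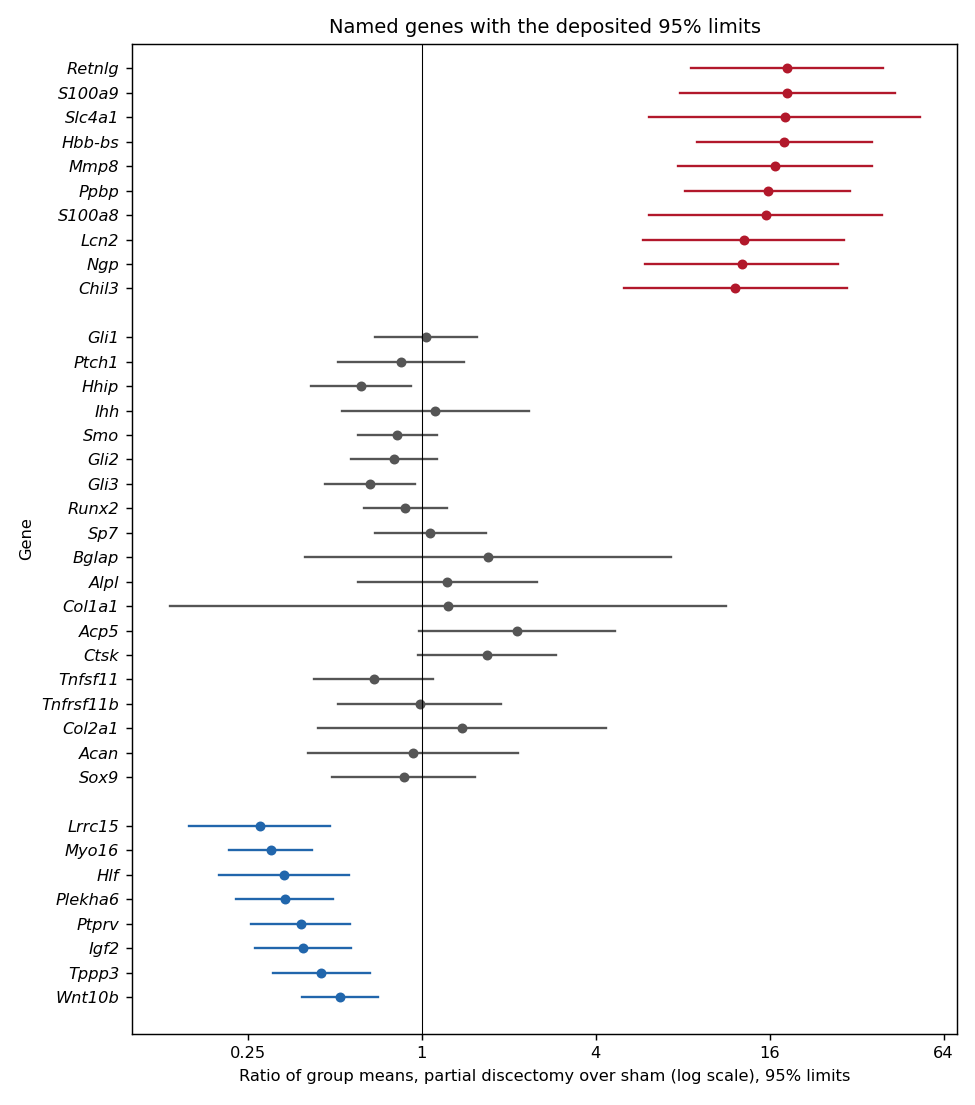
Ratio of group means with 95% limits (horizontal axis, log scale) for the genes named by rule (vertical axis): the 10 largest rises in red, genes chosen in advance in grey and the 8 largest falls in blue. The limits of the red genes lie above 4, those of the blue genes below 0.8, and those of Gli1 run from 0.688 to 1.56.

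Fibrous and tendon genes had no call among 21, with 0 higher and 2 lower at an unadjusted p under 0.05. In the authors' deposited table Fn1 had a ratio of 1.01 and Col3a1 one of 0.629 (0.246 to 1.60). The list's median log2 ratio was -0.15 (adjusted p = 0.00673 towards lower, and 0.0531 with a preset correlation of 0.05). For 3 of the 21 genes the highest library was certain to be a sham library, and without it their median log2 ratio with the floor removed went from -1.49 to -0.84. TGF-beta and BMP genes had 0 calls among 32 (2 higher and 3 lower at an unadjusted p under 0.05), a median log2 ratio of -0.09 and an adjusted p of 0.0451, or 0.175 with a preset correlation of 0.05. Bmpr2 and Bmp1 had ratios of 0.854 and 1.10 in the authors' deposited table. Of 21 matrix proteases and inhibitors 1 rose, Mmp8, the collagenase of neutrophils, and Timp2 had a ratio of 0.624 in the authors' deposited table. Adjusted over that list alone 1 was higher and 2 lower. The adjusted p of the list was 0.492, with a median log2 ratio of -0.03, a mean of 0.16 and a test towards lower. Of 18 inflammation genes 4 rose (5 adjusted over the list alone), namely Il1rn (3.26-fold), Nlrp3 (2.34-fold), Ccl5 (2.88-fold) and Il1b. Each lay under 7 above the floor in the authors' deposited table, and the list had an adjusted p of 0.000362. All 4 are expressed by white blood cells.

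Markers of other tissues and of handling were measured in the same way. Skeletal muscle genes had 0 calls among 24 and none at an unadjusted p under 0.05, yet 22 ratios lay below 1, with 0.411 for Ttn (0.135 to 1.25) and 0.392 for Neb in the authors' deposited table. The muscle list had a median log2 ratio of -0.43, at percentile 0 of matched random lists. Its adjusted p in the list test was 0.0177, or 0.107 with a preset correlation of 0.05 and 0.260 with 0.1. Towards lower too, the adjusted p was 0.00353 by rank, 8.5e-11 with the log2 ratio as the statistic and 9.7e-07 with the floor removed. For 8 of the 24 muscle genes the highest library was certain to be a sham library, with a median of 67.6% of the sham total. Without each gene's highest library, their median log2 ratio with the floor removed went from -1.31 to -0.08. As these genes were picked for a high sham library, a move towards equal means was built in. Among 12 nerve and Schwann cell genes only Mbp rose (2.49-fold, also the only one adjusted over the list alone), with Pmp22 at 0.796, Prx at 0.981 and S100b at 1.27 in the authors' deposited table. Epithelial and salivary genes had 0 calls among 10 (2 higher both at an unadjusted p under 0.05 and adjusted over the list alone), with Krt10 at 0.973 and Amy1 at 1.04 in the authors' deposited table. Of 11 synovial genes Pi16 (3.08-fold) and Dpp4 (2.24-fold) rose in the authors' deposited table, while Prg4, which encodes lubricin, had a ratio of 0.608 (0.150 to 2.47). Adjusted over the list alone 2 were higher and 1 lower. Of 20 hypoxia and vessel growth genes Angpt1 rose (2.01-fold; 2 adjusted over the list alone), with Hif1a at 1.05 and P4ha1 at 1.01 in the authors' deposited table. Notch genes (15) and neurotrophic and pain genes (15) had 0 calls, with 3 higher and 1 lower and with 1 higher and 2 lower at an unadjusted p under 0.05. Notch2, Rbpj, Ntn1 and Ptger1 had ratios of 0.998, 0.918, 0.568 and 1.01 in the authors' deposited table. The adjusted p of the list test was 0.492 for nerve, 0.680 for epithelium, 0.573 for synovium, 0.0605 for hypoxia and vessel growth (0.0462 by rank) and 0.474 for Notch. For the neurotrophic and pain list it was 0.0497 towards lower, and 0.143 with a preset correlation of 0.05. The nerve list had a median log2 ratio of -0.03 and a mean of 0.05.

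Immediate early and stress genes gave 1 call among 22 (1 higher and 2 lower adjusted over the list alone), Btg2 (2.94-fold, 1.82 to 4.74), while Jun and Myc had ratios of 0.877 and 1.06 in the authors' deposited table. Mitochondrially encoded genes gave 0 calls among 13 and none at an unadjusted p under 0.05, with mt-Co1 at 1.00 and mt-Nd4 at 0.864 in the authors' deposited table. The adjusted p of the list test was 0.657 for immediate early and 0.492 for mitochondrial genes, and for the latter the median log2 ratio was 0.01 while the test pointed lower.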

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

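Apart from the false discovery rate of 0.10 and the fold change of at least 2, the alternatives here were chosen after the data were seen. At a false discovery rate of 0.10 there were 889 higher and 75 lower genes, and with a fold change of at least 2 there were 444 and 15. Readjusted over genes with a mean above the floor of at least 5, which tests fewer genes, there were 233 higher and 10 lower genes. The other 4 readjustments gave 429 to 567 higher and 22 to 24 lower genes. The count of deposited 95% limits below equal means, 832, became 1540 when centred on the median of all genes and 2257 when centred on the summed means, while the count above, 2566, became 1878 and 1554. Of the lists, 10 were higher and 6 lower, and the lower ones became 1 with a preset correlation of 0.05, 1 with 0.1 and 3 with ranks. The cause was not tested. Over 7 list settings no list past the threshold changed direction, 6 lists lost a call at least once and 5 gained one. The 121 named genes gave 536 values over the 5 readjustments, as a gene that a setting removes has none there. Only 52 of the 121 genes were called and could lose a call, and 15 of them had a value in all 5 readjustments. Of the 536 values 3 lost a call, each without the 6 blood cell lists (Tppp3 0.0503, Cxcl12 0.0525, Pparg 0.0507). Members of those lists had no value in that setting. For 473 of the 528 genes called higher the highest library was certain to be in partial discectomy. With it set aside for each gene, their median log2 ratio with the floor removed went from 2.24 to 2.02. These genes were chosen by their adjusted p, so a small move was partly built in. No paired analysis was possible because no values per library were analysed here. For the same reason the planned scalings, low-count filters, other count tests, the replicate block, leaving out libraries, an estimated correlation and other splits of the samples were not run. Depth is unknown, and genes near the floor carry the least information.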

Other observations

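The gene groups of this part, and all tests in it except the comparison of B cells with neutrophils and the count of immature granulocyte genes, were chosen after the values were seen. Of 10 heme synthesis genes 4 rose (10 adjusted over the list alone), among them Slc25a37, which carries iron into mitochondria (3.81-fold, 2.36 to 6.13), with a median log2 ratio of 0.90 in the authors' deposited table. Of 6 genes of the phagocyte NADPH oxidase 4 rose, with 4.17-fold for its catalytic subunit Cybb (2.82 to 6.18) and a median of 1.58 in the authors' deposited table. Of 6 red cell membrane skeleton genes 4 rose, Dmtn 5.18-fold, with a median of 1.41. Of 62 histone genes, many of them near-identical copies, 14 rose (52 adjusted over the list alone), with a median of 1.26. Of 10 class II antigen presentation genes only H2-Ob rose (3.91-fold), while Cd74 had a ratio of 1.45 (0.575 to 3.63), with a median of 0.53 in the authors' deposited table.

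Of 10 genes of marrow stroma, put together around genes already seen as called, 4 were called (Cxcl12, Kitl, Ebf3 and Angpt1) and 6 were not, with a median log2 ratio of 0.89. The list of progenitors and marrow stroma fixed in advance had 3 of 17 called and an adjusted p of 0.290. In the authors' deposited table Vcam1 had a ratio of 2.63 (1.15 to 6.02, adjusted p = 0.166) and Lepr one of 1.32. None of 88 ribosomal protein genes was called by the deposited adjusted p or adjusted over the list alone, at an unadjusted p under 0.05 there were 28 higher and 0 lower, and the median was 0.59. Of 7 ribosomal and 7S-type RNAs only Rn7s6 was called (4.28-fold, 1.84 to 9.96), with 1.87 for mt-Rnr1 and a median of 0.90 in the authors' deposited table.

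Neutrophil, erythroid and megakaryocyte genes were higher after partial discectomy, and more marrow or blood in the dissected piece, 1 library or the scale may account for it. A single library was argued against for the 52 measured members as a set, called or not, though not for each gene. The lower quartile of their log2 ratio with the floor removed was 2.22 after each gene's highest value was taken out of the partial discectomy mean. The smallest such ratio was 0.31. For 49 of the 52 that value was certain to come from a partial discectomy library. An earlier form of this test set an upper bound on the median share of the highest library, which the 51.0% found narrowly exceeded, so that it was undecided, and it was replaced after that value was seen and later widened from the 46 called to all members. For marrow with every lineage raised alike, the gap in median log2 ratio between neutrophil and B cell genes was 2.14 with the floor removed. That gap cannot decide it. The megakaryocyte list, itself part of the pattern, had a median of 2.38 against 3.66 for neutrophils, and a ratio also depends on the level in sham. Blood without precursors was argued against by 5 of 7 immature granulocyte genes called higher (Prtn3, Ctsg, Ms4a3, Fcnb and Cebpe). The scale was argued against by a median log2 ratio of 0.14 over genes with a mean above the floor of at least 5. More marrow stays open, whether alike in every lineage or rich in myeloid and erythroid cells. It may have been brought in by the dissection or formed after the operation. The labels do not separate the operation from the dissection or from what the unexplained letters Rctrl and LPD stand for.

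The genes called lower may reflect a smaller share of some tissue in the dissected piece. The osteoblast list as a whole showed no fall, with a lower quartile of its log2 ratios of 0.19. That lay above equal means and little above the 0.13 of the summed group means. No gene of that list had an unadjusted p under 0.05, and its adjusted p in the list test was 0.718. Ratios this uncertain cannot decide on dilution of bone RNA, which stays open. Less fibrous tissue and less muscle stay open, with medians of -0.15 and -0.43 and no called gene in either list. For the 8 muscle genes whose highest library was certain to be in sham, the median log2 ratio went from -1.31 to -0.08 without it. Those genes were picked for a high sham library, so a move towards equal means was built in and does not weigh against less muscle. The other muscle genes were not assessed in this way. Among the 21 called lower genes whose highest library was certain to be in sham the median log2 ratio went from -1.89 to -1.70. These genes were chosen by their adjusted p, so their move cannot be compared with that of the muscle genes. An effect of the operation itself stays open too.

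The Hedgehog list lay below other genes, and a changed mix of tissue may account for it. Both lists compared, 2 of 2 (osteoblast and chondrocyte), had medians above the upper quartile of the Hedgehog list, a log2 ratio of -0.04. The lower quartile of the chondrocyte list, -0.16, lay below that value, and neither list had a called gene. As the Hedgehog list was singled out for lying low, this cannot decide on dilution of all bone and cartilage RNA, which stays open. The median of the fibrous list, -0.15, lay between the limits set for it after the values were seen. Less fibrous tissue stays open, since group means of a mixed tissue cannot tell it apart from a change within cells. The median of the muscle list, -0.43, lay below that of the Hedgehog list, -0.27. By a limit set after the value was known, this goes with less muscle in the dissected piece, which stays open. Whether the Hedgehog RNA of these samples came from muscle was not tested, so a lower muscle list alone cannot give the cause. The 8 muscle genes that went from a median of -1.31 to -0.08 without each gene's highest library were picked for a high sham library. Their move therefore does not weigh against less muscle. A response of Hedgehog genes to the operation stays open and was not tested apart from these.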
